A study of Mus musculus with 18 samples.

How the data were processed

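RNA sequencing had been done on CD4 T cells of female NZB/W F1 mice, hybrids of the NZB and NZW strains that develop a lupus-like disease with age. Per the labels, live CD45+CD19-CD3+CD4+ cells were sorted from spleen and kidney after treatment with an agonist antibody against Ox40 or an IgG1 isotype control, called control Ig here. The groups were 5 kidney libraries with anti-Ox40, 5 kidney libraries with control Ig, 4 spleen libraries with anti-Ox40 and 4 spleen libraries with control Ig, 18 in all. Each library's group came from its organ and treatment labels. The labels carry no replicate numbers, so libraries were numbered within each group in deposition order, and no number pairs libraries. The labels do not say which libraries came from the same mouse, nor that each came from its own mouse, so the p-values measure the spread between these libraries, which may in part be technical.

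Per the labels' protocols, RNA was extracted with column kits, kidney RNA went through an added cleanup kit, and libraries were made with the TruSeq RNA v2 kit from 100 to 500 ng of RNA with 10 cycles of PCR. That kit does not mark the strand, so reads of overlapping antisense genes cannot be told apart. The extraction text also speaks of an in vitro culture before lysis, and the labels do not say whether the sorted cells of these libraries were cultured. GSNAP and the mouse genome build GRCm38 are named in the submitters' processing notes, without a version of the aligner. The annotation, the read length and the treatment of reads with several matches are not given in the sources used here. The values the authors deposited are normalized RPKM (nRPKM, reads per kilobase of gene, relative to the mapped reads of the library and scaled further between libraries), in 1 table of 36528 gene rows. How the scaling was computed is not given in the sources used here, so whether it equalizes organs with different RNA content could not be checked.

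The file had 6 rows without a symbol, 6 rows whose symbol stood on 2 rows and 27 symbols that a spreadsheet had turned into dates; these rows were not named singly. Of the rest, 12381 rows were at 0 in every library and 24141 were above 0 in at least 1. No pair of libraries was identical. Over the 10055 genes at 1 nRPKM or more in every library, at most 0.0895% had equal values in a pair. Gapdh, a gene of glycolysis with many processed copies in the mouse genome, stood at 2.18 to 10.9 nRPKM, a low level for so active a gene. Values of genes with near-identical copies are uncertain. Such genes were left out in an alternative fit of kidney against spleen, but they were kept in every fit of the treatment effects.

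Depth was estimated from the steps between low values, since a low gene's values are multiples of what 1 read is worth. The estimates, in M reads on genes, were 7.08 to 14.1 for kidney anti-Ox40, 7.96 to 17.3 for kidney control Ig, 20.2 to 23.7 for spleen anti-Ox40 and 17.98 to 23.4 for spleen control Ig. They are approximate: in 4935 low genes, 56.2% of values lay within 0.1 of a whole read and 39.1% of genes had every value within that tolerance, so whole reads were not recovered and no count test was run. At these depths 1 read in a gene of 2 kb was worth 0.0244 to 0.0773 nRPKM.

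Values were tested as log2(nRPKM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). A fold change on this scale understates the change of low genes. Every adjusted p of a gene is from limma. Genes with 1 nRPKM or more in at least 4 of the fitted libraries were tested. The effect of anti-Ox40 was fitted within each organ. The difference between the effects in kidney and spleen, and kidney against spleen under each treatment, were fitted over all 18 libraries with 4 group means. The design table had left room for counts; since the file held nRPKM, the test planned for normalized values was used.

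The gene lists, 38 in number, were fixed before the data were examined: T cell states, helper subsets, cytokines, interferon responses, cell cycle, metabolism, and markers of other cells that a sort could hold. Lists with at least 3 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01, which gave 30 lists in the kidney, 28 in the spleen and 31 over all libraries. Each was also tested with camera's estimated correlation and with fry. A member counted as risen or fallen after adjustment over all genes tested, and again adjusted over the list alone. A list score is the mean log2 value of the members in a library.

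Named genes followed a rule fixed before the data were examined. For each treatment comparison they were Tnfrsf4, Tnfsf4, Foxp3, Il10, Tbx21, Ifng, Bcl6, Il21, Cxcr5, Pdcd1, Gata3, Il4, Rorc, Il17a, Gzmb, Gzmk, Sell, Ccr7 and Mki67 whether or not they passed; the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap; and up to 4 members per list with the smallest p. For the difference of effects they were the 6 largest in each direction. For the organs they were the 10 largest in each direction with groups that did not overlap, and the fixed genes. Receptor segments, predicted genes and small RNAs were to be left out; Scarna17 and the sequence-tag gene AW011738 passed the rule as written and were kept. Il17a was below the filter in both organs. Tnfsf4 and Rorc were below it in the spleen.

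Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean of 5 nRPKM or more, quantile normalization, median-of-ratios rescaling, no trend in the variance prior, library weights, other sets of libraries in the fit, and leaving out each replicate. Another planned pair of alternatives concerned the 2 kidney libraries, replicate 5 of each treatment, whose sample identifiers come from another run of numbers: a term for that run, and a fit without them. Added after the data were seen were scores of the macrophage and mitosis lists and the relative depth as covariates, and fits without 697 genes that followed the macrophage score across kidney libraries (correlation 0.8 or more) or without 571 genes with 10% or more of their 50-base stretches in an annotated pseudogene. Pseudogene sequence and gene positions came from GENCODE mouse release M21, which uses GRCm38. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for the rest.

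The fits were tested on simulated data with changes added to 200 genes. The simulated noise was normal and independent between genes, whereas genes of the real libraries vary together. The figures are therefore not error rates for the real data. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 44.8%, 85.1% and 97.0% of genes in the kidney design, where 15 of 166 calls were false. The figures were 71.6%, 94.0% and 100% in the spleen design, with 5 of 182 calls false. For the difference of effects they were 25.4%, 80.6% and 97.0%, with 12 of 147 calls false. They were 47.8%, 91.0% and 97.0% for kidney against spleen under control Ig, with 7 of 164 calls false. Under anti-Ox40 they were 50.7%, 88.1% and 97.0%, with 10 of 167 calls false.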

Results

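CD4 T cells were sequenced from the spleen and kidney of female NZB/W F1 mice, a hybrid strain with spontaneous lupus-like autoimmunity and nephritis. The mice had been given an agonist antibody against Ox40 or an isotype control IgG1 under the skin at 10 mg/kg, 3 times a week for 1 to 1.5 weeks. Ox40, encoded by Tnfrsf4, is a costimulatory receptor of activated T cells in the TNF receptor superfamily, and its ligand is encoded by Tnfsf4. Per its title and design text, the series asked how the agonist acts in mice whose lupus it made worse. The protocol describes cohorts of 12 to 13 weeks and of 21 to 27 weeks of age, and the labels do not say which cohort gave these libraries. There were 5 kidney and 4 spleen libraries for each treatment. The estimated depth was 7.08 to 17.3M reads on genes in kidney libraries and 17.98 to 23.7M in spleen libraries, so low genes were measured less precisely in the kidney. The spread between replicates was also larger there, with a median residual SD of 0.19 on the log2 scale in the kidney and 0.10 in the spleen. The axis of largest variance, with 52.3% of the total, separated all 10 kidney libraries from all 8 spleen libraries. The second axis, with 10.7%, set kidney anti-Ox40 replicate 1 apart, at 51.8 where the other libraries lay between -23.9 and 5.83. That library had the lowest depth and the fewest genes above 0, 14331. Without it 456 genes were called in the kidney and 152 for the difference of effects.

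The first question was what the agonist changed in CD4 T cells of the kidney. Gzmb, which encodes the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260), had the largest rise at the pseudocount of 1, whereas at 0.1 Gcg rose more (4.13 against 3.15 for Gzmb). Gzmb stood at 55.8 ± 24.8 nRPKM with anti-Ox40 and 5.81 ± 1.74 with control Ig (mean ± SD, n = 5 each), a log2 fold change of 2.96 ± 0.30 (SE; adjusted p = 0.00269). Mki67, the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716361), rose from 10.5 ± 1.97 to 30.6 ± 13.2 nRPKM (log2 fold change 1.38 ± 0.25, adjusted p = 0.018). Il2ra, the alpha chain of the high-affinity IL-2 receptor (chromosome 2, 11642807 to 11693193), rose from 12.2 ± 1.79 to 27.4 ± 1.68 nRPKM (log2 fold change 1.11 ± 0.10, adjusted p = 0.00149). Ccr7, the chemokine receptor that brings naive T cells to lymph nodes (chromosome 11, 99144196 to 99155077), fell from 148 ± 19.7 to 76.6 ± 26.1 nRPKM (log2 fold change -0.996 ± 0.20, adjusted p = 0.0228), and this call was lost without control Ig replicate 1 or without replicate 2. In each of these 4 genes the 5 treated libraries lay beyond all 5 controls. In all, 434 genes were higher and 204 lower among 12303 tested; 105 of the former and 10 of the latter changed by 2-fold or more.

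Of the 22 measured members of the DNA replication and S phase list, 20 rose in the kidney and none fell (22 when adjusted over the list alone, median log2 fold change 1.05, camera adjusted p = 5.93e-23, and adjusted p = 0.088 with an estimated correlation). The replication licensing factor Mcm6 rose from 48.5 ± 4.18 to 90.0 ± 14.5 nRPKM and its partner Mcm2 from 20.5 ± 2.21 to 47.3 ± 11.5. Uhrf1, which maintains DNA methylation at replication (chromosome 17, 56303321 to 56323486), rose from 5.53 ± 0.756 to 19.6 ± 6.86 nRPKM (log2 fold change 1.60 ± 0.21, adjusted p = 0.00714). In the mitosis list, 18 of 25 members rose and none fell (24 adjusted over the list alone, median 1.19, camera adjusted p = 6.45e-18, and adjusted p = 0.117 with an estimated correlation). Without a library this was 3 to 23, and 14 to 21 for the S phase list. Top2a, the topoisomerase that untangles replicated DNA, rose from 15.9 ± 3.27 to 46.7 ± 19.2 nRPKM. Rrm2, a subunit of ribonucleotide reductase, rose from 13.8 ± 2.52 to 45.5 ± 21.1. Other large rises were in Gcg, Ccl1, Ckap2l, Esco2, Shcbp1, Ccna2 and Asf1b, with log2 fold changes of 1.51 to 2.32. Leaving out a library ended the call of Ccl1 and of Ccna2 in 6 of 10 fits, of Ckap2l in 5 and of Shcbp1 in 3. Gcg, the gene of the glucagon precursor (chromosome 2, 62474530 to 62483650), stood at 6.89 ± 5.38 nRPKM with anti-Ox40 and 0.321 ± 0.300 with control Ig (log2 fold change 2.32 ± 0.43, adjusted p = 0.0185).

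The naive and central memory T cell list moved the other way, with 7 of 15 members lower and none higher (all 15 lower when adjusted over the list alone, median log2 fold change -0.65, camera adjusted p = 9.68e-11, and adjusted p = 0.117 with an estimated correlation). Without a library 1 to 11 members were called, 1 without control Ig replicate 1 or without replicate 2. Besides Ccr7, the IL-7 receptor gene Il7r fell from 188 ± 15.2 to 112 ± 35.7 nRPKM, and the transcription factor genes Satb1 and Foxp1 fell by 0.72 and 0.55 on the log2 scale. The Il7r call was lost in 8 and the Foxp1 call in 5 of the 10 fits that left out a library. Sell, the lymph node homing receptor L-selectin, was at 34.6 ± 8.88 nRPKM with anti-Ox40 and 53.6 ± 11.3 with control Ig, which did not pass the threshold (adjusted p = 0.0738). Other large falls were in Acss2os, Vipr1, Cd55, Lypd6b, St8sia6 (lost in 4 of 10 such fits), Fam101b (5), Bambi-ps1 (3) and Klf3 (2). Vipr1, a receptor of vasoactive intestinal peptide (chromosome 9, 121642716 to 121672954), fell from 30.9 ± 4.56 to 14.7 ± 3.13 nRPKM (log2 fold change -1.03, adjusted p = 0.0102). Acss2os is antisense to another gene, and reads of the pair cannot be told apart without strand.

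Among lists of T cell function in the kidney, 6 of 19 activation genes rose (9 adjusted over the list alone, median 0.35, camera adjusted p = 4.89e-06, and adjusted p = 0.088 with an estimated correlation), led by Il2ra, Tnfrsf18, Batf and Il2rb (lost in 2 of 10 fits that left out a library). In the cytotoxicity list 6 of 21 rose and none fell (7 higher and 1 lower adjusted over the list alone, median 0.50, camera adjusted p = 6.19e-06, and adjusted p = 0.088 with an estimated correlation). Nkg7, a protein of cytotoxic granules, rose from 52.5 ± 11.02 to 106 ± 24.1 nRPKM. In the T cell cytokine list 3 of 14 rose (6 adjusted over the list alone, median 0.47, camera adjusted p = 1.65e-05), and this was the list call in the kidney that held with an estimated correlation (adjusted p = 0.0379). These were Lta, Csf1 and Csf2, the gene of the growth factor GM-CSF, which stood at 4.91 ± 2.68 nRPKM against 0.521 ± 0.419, with overlapping groups (log2 fold change 1.83 ± 0.37, adjusted p = 0.0229). The Csf2 call was lost in 5 and the Csf1 call in 7 of the 10 fits that left out a library. Of the inhibitory receptors 3 of 12 rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0002, and adjusted p = 0.113 with an estimated correlation). Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553), rose from 41.7 ± 9.004 to 80.2 ± 11.8 nRPKM (log2 fold change 0.94 ± 0.14, adjusted p = 0.0129). The other calls in this list, Entpd1 and Pdcd1lg2, were lost in 8 and 7 of the 10 fits that left out a library.

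The regulatory T cell list had 3 of 17 members higher in the kidney (6 adjusted over the list alone, camera adjusted p = 5.97e-06, and adjusted p = 0.117 with an estimated correlation), namely Il2ra, Tnfrsf18 and Capg. Lists share members, so their tests are not independent. Il2ra and Tnfrsf18 are also in the activation list, and Tnfrsf18 is in the TNF superfamily list. Birc5 is shared by the mitosis and apoptosis lists, and Bcl2l1 by the NF-kB and apoptosis lists. Nkg7 is in the cytotoxicity and Th1 lists, and Pdcd1 in the inhibitory receptor and T follicular helper lists. Foxp3, the lineage factor of regulatory T cells (chromosome X, 7573644 to 7595245), was at 59.0 ± 10.1 against 37.6 ± 9.17 nRPKM and did not pass (adjusted p = 0.0538). Of the TNF superfamily list 5 of 22 rose (8 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0057, and adjusted p = 0.088 with an estimated correlation). The Ox40 ligand gene Tnfsf4 (chromosome 1, 161395409 to 161418410) was low, at 1.72 ± 0.622 against 0.436 ± 0.358 nRPKM (adjusted p = 0.0354, a call lost in 8 of 10 fits that left out a library). Tnfrsf4 itself (chromosome 4, 156013843 to 156016612) was at 32.9 ± 4.78 against 25.1 ± 3.55 nRPKM (adjusted p = 0.079). Of the glycolysis genes 5 of 15 rose (9 adjusted over the list alone, camera adjusted p = 1.31e-06, and adjusted p = 0.088 with an estimated correlation), with Ldha, Pkm, Tpi1 and Slc16a3 (lost in 1 of 10 such fits) in front. In the apoptosis and survival list 6 of 16 rose (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000839, and adjusted p = 0.0782 with an estimated correlation), Casp3 by 0.79 and Birc5 by 1.16 on the log2 scale (Birc5 lost in 6 of 10 such fits). In the NF-kB target list 3 of 17 rose (3 adjusted over the list alone, camera adjusted p = 0.000525, and adjusted p = 0.117 with an estimated correlation), Icam1, Bcl2l1 (lost in 6 of 10 such fits) and Bcl3 (in 8). In the oxidative phosphorylation list 1 of 18 rose, Cox5a (2 adjusted over the list alone, camera adjusted p = 2.8e-05, and adjusted p = 0.199 with an estimated correlation). The Cox5a call was lost in 7 of 10 such fits. No member of the tissue residency list passed (camera adjusted p = 0.00901, and adjusted p = 0.088 with an estimated correlation). The lists of MYC targets, cholesterol synthesis, homing receptors and the identity of the sorted cells did not pass (camera adjusted p = 0.17, 0.628, 0.311 and 0.628).

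Few helper lineage genes passed in the kidney. Ifng, the gene of interferon gamma, was at 78.7 ± 14.9 against 65.3 ± 5.71 nRPKM (log2 fold change 0.25, adjusted p = 0.275). Tbx21, Bcl6, Gata3, Il4, Rorc, Cxcr5, Gzmk and Il21 also stayed short of the threshold, with log2 fold changes of -0.16 to 0.77, and Il10 was at 16.9 ± 8.21 against 9.88 ± 6.35 nRPKM (adjusted p = 0.295). Of the Th1 list 2 of 15 rose, Nkg7 and Il12rb1 (2 adjusted over the list alone, camera adjusted p = 0.0108, and adjusted p = 0.425 with an estimated correlation). In the T follicular helper list 1 of 15 rose, Pdcd1 (3 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.425 with an estimated correlation). The Th2 list (median 0.28, camera adjusted p = 0.0606) and the Th17 list (median -0.04, mean 0.03, camera adjusted p = 0.636) did not pass. Of the type I interferon list 2 of 28 rose, Rtp4 and Oas1a (3 adjusted over the list alone, median 0.21, camera adjusted p = 0.000142, and adjusted p = 0.441 with an estimated correlation). Of the interferon gamma list 6 of 19 rose (12 adjusted over the list alone, median 0.25, camera adjusted p = 9.49e-07, and adjusted p = 0.117 with an estimated correlation), each by a small step such as 0.32 for Gbp2. Of these calls Oas1a and Gbp2 were each lost in 6 and Il12rb1 in 4 of the 10 fits that left out a library. The interferon gamma list calls of Socs1, Psmb8 and Gbp3 were lost in 8, 7 and 6 of those fits.

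Markers of other cells were present in the kidney libraries and varied between them. The macrophage score was 3.85 ± 0.692 with anti-Ox40 and 4.29 ± 0.847 with control Ig on the log2 scale. No member of the macrophage list passed in the kidney, and its median log2 fold change was -0.39 (camera adjusted p = 0.0366, and adjusted p = 0.664 with an estimated correlation). The kidney tubule score was 1.63 ± 0.272 against 1.58 ± 0.488, with 1 of 13 members, Epcam, higher (1 adjusted over the list alone, camera adjusted p = 0.759). Of the 3 endothelial markers Ehd3 fell (2 adjusted over the list alone, camera adjusted p = 0.0372, and adjusted p = 0.117 with an estimated correlation). The dendritic cell and NK cell marker lists did not pass (camera adjusted p = 0.628 and 0.498). Cd8a was at 4.33 against 3.03 nRPKM and Cd8b1 at 9.63 against 8.80, neither past the threshold. The score of RNA quality and nuclear RNA was 3.46 ± 0.0797 with anti-Ox40 and 3.64 ± 0.112 with control Ig, and its 2 tested genes, too few for a list test, did not pass (Malat1 -0.41 and Neat1 -0.29 on the log2 scale, adjusted p = 0.296 and 0.295). The mitochondrial genes of that list were matched to no row, so the score rests on Malat1, Neat1, Meg3 and Kcnq1ot1 alone. The immediate early and stress list was lower, with 1 of 19 members past the threshold (1 lower and 1 higher adjusted over the list alone), Jun at 147 ± 67.2 against 270 ± 33.8 nRPKM (camera adjusted p = 0.00126, and adjusted p = 0.441 with an estimated correlation). With fry the calls of the Th1, T follicular helper, type I interferon, macrophage and immediate early lists were lost in the kidney, 5 of 21. Leaving out a library ended the Jun call in 9 of 10 fits, the Ehd3 call in 8 and the Epcam call in 5. The count of 638 called genes depended on single libraries: it was 153 without anti-Ox40 replicate 5 and 4 without both replicates numbered 5, whose identifiers come from another run of numbers. The 4 were Il2ra, Cish, Mcm6 and Capg (Cish was named after the values were seen), and Gzmb kept a log2 fold change of 2.86 there with an adjusted p of 0.0511; with a term for the identifier run, 651 genes passed.

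**Figure D1:**
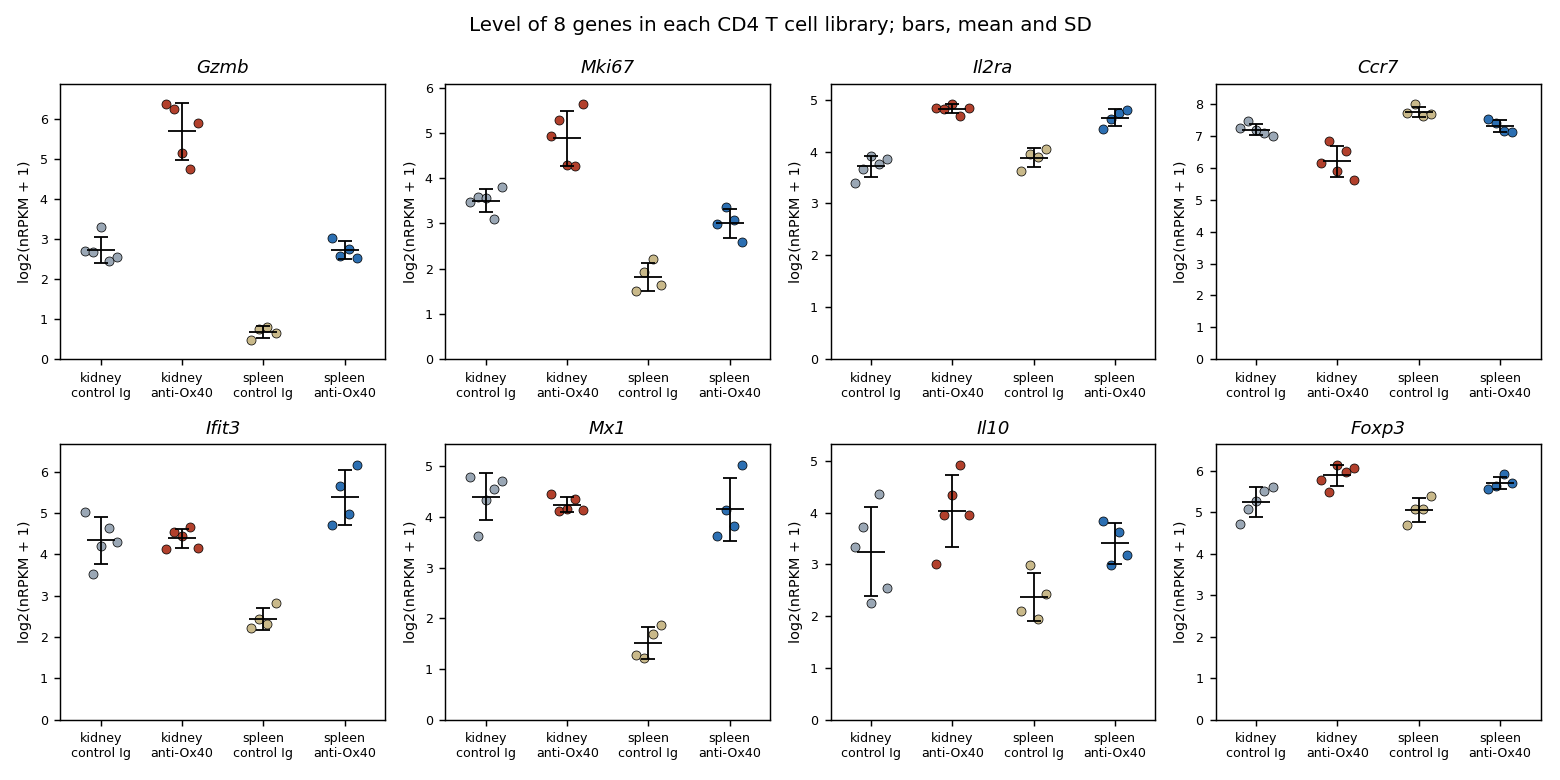
Level of 8 genes in each library, as log2(nRPKM + 1), for 5 kidney and 4 spleen libraries per treatment; points are libraries and bars are mean and SD. Gzmb and Mki67 were higher with anti-Ox40 in both organs, whereas Ifit3 and Mx1 differed between treatments in the spleen and overlapped in the kidney.

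The same comparison in the spleen had Ifit3, Oasl2, Ccl3, Ccl4 and Mx1 as the largest rises among the named genes, at the pseudocount of 1. Ifit3, an antiviral protein induced by type I interferon (chromosome 19, 34583531 to 34588731), rose from 4.53 ± 1.09 nRPKM with control Ig to 44.0 ± 20.7 with anti-Ox40 (mean ± SD, n = 4 each; log2 fold change 2.93 ± 0.29, adjusted p = 0.000782). Mx1, an interferon-induced GTPase (chromosome 16, 97447035 to 97462907), rose from 1.92 ± 0.639 to 18.2 ± 9.29 nRPKM. Isg15 rose from 12.6 ± 2.12 to 66.9 ± 28.4 and Stat1, a transcription factor of interferon signalling, from 137 ± 13.4 to 306 ± 44.4. All 28 measured members of the type I interferon list rose (28 adjusted over the list alone, median log2 fold change 1.64, camera adjusted p = 2.21e-35, and adjusted p = 0.154 with an estimated correlation). All 17 members of the interferon gamma list rose too (17 adjusted over the list alone, median 1.17, camera adjusted p = 1.64e-24, and adjusted p = 0.154 with an estimated correlation), with Gbp2, Igtp, Gbp7 and Irgm1 up by 1.17 to 1.48 on the log2 scale. Of 11671 genes tested, 611 were higher and 395 lower; 105 rose and 2 fell by 2-fold or more. Quantile normalization gave 563 higher and 537 lower.

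In the spleen Gzmb rose from 0.603 ± 0.159 to 5.67 ± 1.11 nRPKM (log2 fold change 2.05 ± 0.12, adjusted p = 0.000262). Gzmk, which encodes granzyme K (chromosome 13, 113171608 to 113225908), rose from 1.49 ± 0.389 to 8.31 ± 2.15 (log2 fold change 1.89 ± 0.17, adjusted p = 0.000696). The chemokine genes Ccl3 and Ccl4 rose from 0.423 ± 0.207 to 8.73 ± 4.34 and from 0.807 ± 0.519 to 10.8 ± 5.301 nRPKM. In the cytotoxicity list 10 of 20 members rose and 2 fell (11 and 4 adjusted over the list alone, median 0.34, camera adjusted p = 0.000126, and adjusted p = 0.192 with an estimated correlation), and Klrd1, a lectin-like receptor of NK and T cells, was among the falls. Mki67 rose from 2.59 ± 0.788 to 7.18 ± 1.77 nRPKM (log2 fold change 1.19, adjusted p = 0.00491). In the mitosis list 11 of 16 rose (13 adjusted over the list alone, median 0.68, camera adjusted p = 9.61e-10, and adjusted p = 0.197 with an estimated correlation). In the S phase list 6 of 20 rose (15 adjusted over the list alone, median 0.27, camera adjusted p = 2.56e-09, and adjusted p = 0.154 with an estimated correlation).

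In the regulatory T cell list 9 of 16 rose in the spleen, and 3 did without anti-Ox40 replicate 4 (15 adjusted over the list alone, median 0.63, camera adjusted p = 1.35e-10, and adjusted p = 0.192 with an estimated correlation). Foxp3 rose from 32.8 ± 6.52 to 51.4 ± 5.82 nRPKM (log2 fold change 0.65, adjusted p = 0.0177), a call lost without anti-Ox40 replicate 3 or without replicate 4, and Lrrc32 and Ikzf2 rose by 0.88 and 0.69. Il10, an anti-inflammatory cytokine gene (chromosome 1, 131019845 to 131024974), was at 9.90 ± 2.93 against 4.38 ± 1.83 nRPKM with overlapping groups (log2 fold change 1.04 ± 0.24, adjusted p = 0.0307), and its call was lost in 6 of 8 fits that left out a library. In the T follicular helper list 5 of 16 rose (8 adjusted over the list alone, median 0.49, camera adjusted p = 2.04e-07, and adjusted p = 0.282 with an estimated correlation), among them Icos, Slamf6 (lost in 1 of 8 such fits), Cd200 (in 3) and S1pr2 (in 3). Bcl6, the lineage factor of these cells, and Cxcr5 did not pass (log2 fold changes 0.13 and 0.45). Of the inhibitory receptors 6 of 11 rose and 1, Cd160 (lost in 2 of 8 such fits), fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.000488, and adjusted p = 0.297 with an estimated correlation). Lag3 rose from 17.7 ± 6.32 to 49.9 ± 10.9 nRPKM, and Pdcd1 was at 44.7 ± 9.77 against 27.1 ± 6.38 (adjusted p = 0.0442, lost in 5 of 8 fits that left out a library).

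The activation list had 7 of 19 members higher in the spleen (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.04e-07, and adjusted p = 0.154 with an estimated correlation), with Il2ra up from 13.8 ± 1.80 to 24.3 ± 2.70 nRPKM. Tnfrsf4 was at 23.1 ± 3.27 against 16.9 ± 1.93 nRPKM (log2 fold change 0.42, adjusted p = 0.0385), a call lost in 5 of 8 fits that left out a library. In the NF-kB target list 5 of 17 rose (11 adjusted over the list alone, camera adjusted p = 3.07e-07, and adjusted p = 0.154 with an estimated correlation). Of the naive T cell list 8 of 15 fell (10 adjusted over the list alone, median -0.30, camera adjusted p = 7.28e-07, and adjusted p = 0.175 with an estimated correlation). Dapl1, a gene of resting T cells (chromosome 2, 59484653 to 59505020), fell from 45.9 ± 6.24 to 25.8 ± 4.13 nRPKM (log2 fold change -0.81). Ccr7 was at 159 ± 20.4 against 218 ± 26.7 nRPKM (adjusted p = 0.0295, lost in 4 of 8 fits that left out a library), and Sell did not differ detectably (log2 fold change -0.00, adjusted p = 0.989). Other large falls were in Slc16a5, Klrd1, Emid1, Cd7, Ldlr, Adh1, Eya2, Ctla2a and Dand5, from -0.82 to -0.63 on the log2 scale. Of the cholesterol synthesis list 4 of 16 fell, Dhcr24, Sqle, Srebf2 and Ldlr, the last 2 lost in 1 and 5 of 8 such fits (9 adjusted over the list alone, camera adjusted p = 2.04e-06, and adjusted p = 0.274 with an estimated correlation).

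Ifng in the spleen was at 9.83 ± 2.33 against 10.5 ± 3.46 nRPKM (log2 fold change -0.05, adjusted p = 0.928), and Tbx21, Gata3, Il4 and Il21 did not pass. In the Th1 list 4 of 14 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0382, and adjusted p = 0.282 with an estimated correlation). In the TNF superfamily list 6 of 20 rose and 1 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0289, and adjusted p = 0.349 with an estimated correlation), with Tnfsf8, Tnfsf10, Tnfrsf14 and Tnfrsf1b in front, the last 2 each lost in 3 of 8 fits that left out a library. In the apoptosis and survival list 4 of 13 rose, Casp3, Casp8, Bcl2 and Pmaip1, the last 2 lost in 1 and 4 of 8 such fits (7 adjusted over the list alone, camera adjusted p = 0.00299, and adjusted p = 0.154 with an estimated correlation). The T cell cytokine list did not pass (camera adjusted p = 0.312), with Csf1 and Il10 higher (3 adjusted over the list alone). Of the 3 dendritic cell markers tested, Bst2, Cd74 and H2-Eb1, all rose (3 adjusted over the list alone, camera adjusted p = 9.36e-05, and adjusted p = 0.154 with an estimated correlation). Bst2 is also in the type I interferon list. Cd74, the invariant chain of MHC class II, rose from 8.62 ± 2.27 to 21.6 ± 4.55 nRPKM. The macrophage score was 1.50 ± 0.125 against 1.35 ± 0.0322, and the kidney tubule score 0.205 ± 0.0209 against 0.166 ± 0.0140, both far below the kidney libraries. The B cell score (0.476 ± 0.0428 against 0.376 ± 0.0412) and the dendritic cell score (1.19 ± 0.0945 against 0.850 ± 0.0513) were also higher with anti-Ox40. The endothelial, CD8 T cell and gamma delta T cell scores were lower. Ccl3 and Ccl4, which rose in the spleen, followed the macrophage score across kidney libraries (r = 0.90 and 0.85). Whether other cells carried part of the spleen rises was not tested. The score of RNA quality and nuclear RNA, again without mitochondrial genes, was 3.95 ± 0.0667 against 3.78 ± 0.170, and neither Malat1 (log2 fold change 0.55, adjusted p = 0.0957) nor Neat1 (0.09, adjusted p = 0.700) passed. No list call in the spleen held with an estimated correlation, and fry ended those of Th17, inhibitory receptors, TNF superfamily and glycolysis, 4 of 20. The Th17 score was 0.836 ± 0.0431 with anti-Ox40 and 0.721 ± 0.115 with control Ig, and the glycolysis score 3.78 ± 0.0425 and 3.64 ± 0.0588. Among glycolysis calls, Tpi1 and Pfkp were each lost in 7 and Slc16a3 in 4 of 8 fits that left out a library. The count of 1006 genes was 515 without anti-Ox40 replicate 4, and each of the 8 fits that left out a library kept at least 27 of the 28 type I interferon calls.

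**Figure D2:**
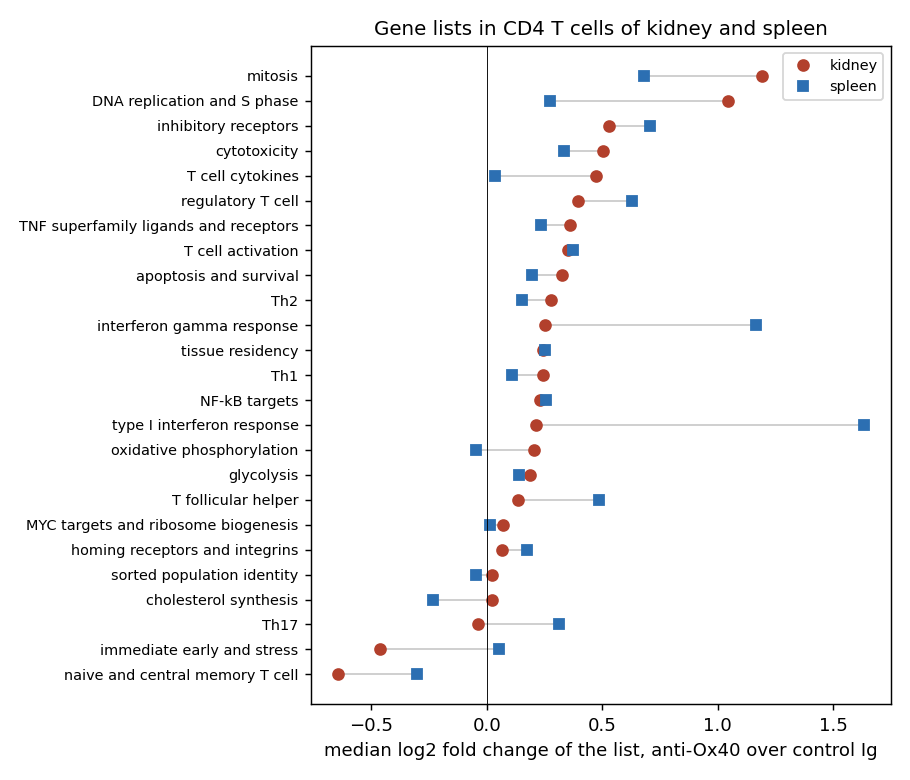
Median log2 fold change, anti-Ox40 over control Ig, of 25 gene lists fixed before the data were examined, with a circle for kidney and a square for spleen. The type I interferon list stood at 0.21 in the kidney and 1.64 in the spleen, and the S phase list at 1.05 and 0.27.

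Whether the agonist acted differently in the 2 organs was tested as the difference between the kidney and the spleen effect. Interferon-response genes held the 6 largest differences among the named genes. For Ifit3 the kidney effect was lower than the spleen effect by 2.88 ± 0.40 on the log2 scale (difference -2.88, adjusted p = 0.0014), with 20.1 ± 3.38 nRPKM under anti-Ox40 and 20.4 ± 7.93 under control Ig in the kidney. For Mx1 the difference was -2.79 ± 0.36 (adjusted p = 0.00107), with kidney levels of 18.1 ± 2.08 and 21.0 ± 6.08 nRPKM. Ifi44, Oasl2, Rsad2 and Ifit1 had differences of -2.50 to -2.23. In the type I interferon list 26 of 28 members differed, all with the lower effect in the kidney (28 adjusted over the list alone, median difference -1.24, camera adjusted p = 4.47e-44). In the interferon gamma list 12 of 19 did so (14 adjusted over the list alone, median -0.89, camera adjusted p = 3.19e-19). With an estimated correlation both calls held, at an adjusted p of 0.04996, which is just under the threshold.

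The kidney effect was the higher one for Mcm2 (chromosome 6, 88883474 to 88898780), with a difference of 0.94 ± 0.19 (adjusted p = 0.0194), a call lost in 2 of 18 fits that left out a library. In the S phase list 3 of 22 members differed (15 adjusted over the list alone, median 0.70, camera adjusted p = 5.38e-16, and adjusted p = 0.228 with an estimated correlation). In the mitosis list no member passed (none adjusted over the list alone, median 0.65, camera adjusted p = 3.59e-07, and adjusted p = 0.55 with an estimated correlation). The mitosis score was low in the spleen, 0.987 with control Ig and 1.53 with anti-Ox40, against 2.20 and 3.34 in the kidney. The scale understates changes of low genes, so part of this difference can come from the scale. Mki67, for example, rose from 10.5 to 30.6 nRPKM in the kidney and from 2.59 to 7.18 in the spleen. Gzmc, which encodes granzyme C (chromosome 14, 56231441 to 56234656), was at 3.41 ± 1.49 against 0.592 ± 0.617 nRPKM in the kidney and at 0.434 against 0.475 in the spleen (difference 1.53 ± 0.36, adjusted p = 0.0426), a call lost in 13 of 18 fits that left out a library. Ctla2a, Dapk2 and Lsm3 had differences of 0.91 to 1.34, each lost in more than 10 of those fits. Scarna17, a small nuclear RNA near the detection limit, had a difference of 1.82. Its call held without each library in turn and in every alternative fixed beforehand in which it was tested. For the naive T cell list the difference had a median of -0.42 with no member past the threshold (camera adjusted p = 0.000406, and adjusted p = 0.55 with an estimated correlation). With fry 8 of 11 list calls for the difference were lost, mitosis and naive T cells among them, and the 2 interferon lists and the S phase list held. In all, 50 genes had the higher effect in the kidney and 115 the lower one, among 12777 tested, and this count was 80 (7 and 73) without spleen anti-Ox40 replicate 4 and 392 (206 and 186) without kidney anti-Ox40 replicate 4.

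**Figure D3:**
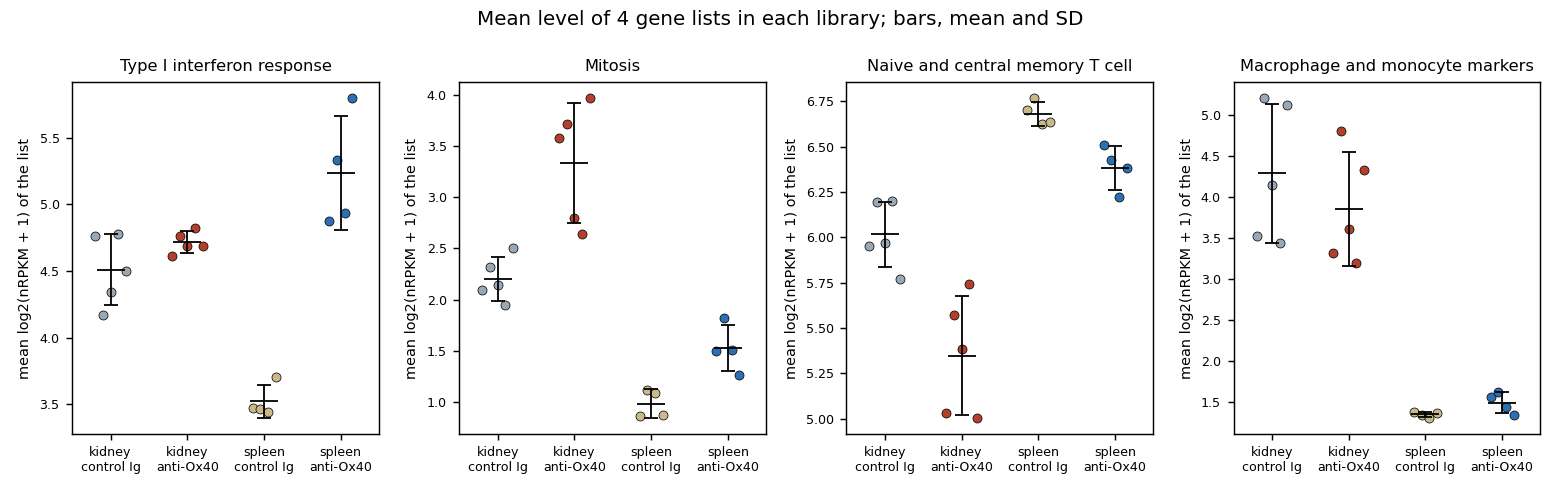
Mean log2(nRPKM + 1) over the members of 4 gene lists in each library; points are libraries, bars are mean and SD, and the vertical axes do not start at 0. The type I interferon score was 3.52 in spleen control Ig, 5.23 in spleen anti-Ox40, and 4.51 and 4.72 in kidney control Ig and anti-Ox40.

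Across the 11353 genes tested in both organs, the 2 treatment effects had a Pearson r of 0.320 and a Spearman rho of 0.254, described across genes, which are not independent replicates. The 2 comparisons share no library. Genes higher in both organs numbered 112, where independent lists would share 19.7, and genes lower in both numbered 50, where 6.90 would be shared. The 112 included Gzmb, Gcg, Mki67, Il2ra, Nkg7 and Casp3, and Ccr7 was lower in both; the Nkg7 call in the spleen was lost in 4 of 8 fits that left out a library. Calls in opposite directions were rare: 1 gene was higher in the kidney and lower in the spleen, where independent lists would share 12.8, and none was lower in the kidney and higher in the spleen, where 10.6 would be shared. That gene was Ercc1, a DNA repair gene named after the values were seen, with log2 fold changes of 0.34 and -0.24.

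**Figure D4:**
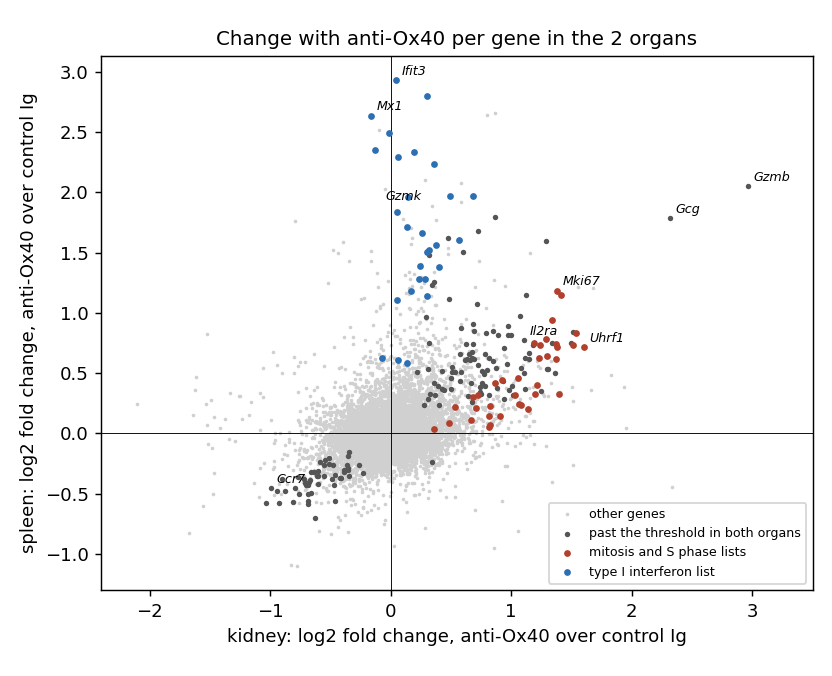
Log2 fold change with anti-Ox40 in the kidney (horizontal axis) against the spleen (vertical axis) for 11353 genes tested in both; each point is a gene. Type I interferon genes lie along the vertical axis, and genes of mitosis and S phase lie to the right.

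The organs themselves were compared under control Ig. Ifng (chromosome 10, 118441046 to 118445892) was at 65.3 ± 5.71 nRPKM in the kidney (n = 5) and 10.5 ± 3.46 in the spleen (n = 4), a log2 difference of 2.58 ± 0.20 (adjusted p = 5.03e-08). Gzmk was at 21.9 ± 2.76 against 1.49 ± 0.389, Tbx21, the Th1 lineage factor, at 35.9 ± 8.72 against 13.4 ± 1.43, and Gata3, the Th2 lineage factor, at 43.0 ± 3.69 against 25.1 ± 1.80. Dtx1, a regulator of Notch signalling (chromosome 5, 120680202 to 120711927), was lower in the kidney, at 36.8 ± 5.09 against 132 ± 4.91 nRPKM. Foxp3, Il10, Bcl6, Il21, Cxcr5, Il4, Rorc and Tnfsf4 did not pass. Of 12777 genes, 2247 were higher and 2006 lower in the kidney, and 647 and 125 of these by 2-fold or more; quantile normalization turned this split into 1869 higher and 2719 lower.

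In the tissue residency list 15 of 17 members were higher in the kidney under control Ig (15 adjusted over the list alone, median 1.14; adjusted p = 0.00229 with an estimated correlation). So were 14 of 15 in the Th1 list (14 adjusted over the list alone, median 1.54; adjusted p = 0.0355 with an estimated correlation) and 5 of 9 in the Th2 list (5 adjusted over the list alone, median 0.75; adjusted p = 0.0355 with an estimated correlation). The apoptosis and survival list had 11 members higher and 2 lower of 16 (11 and 2 adjusted over the list alone; adjusted p = 0.0178 with an estimated correlation). These 4 list calls held with an estimated correlation. Type I interferon genes were higher in 23 of 28 cases (24 adjusted over the list alone, median 0.91, camera adjusted p = 8.89e-12, and adjusted p = 0.161 with an estimated correlation). In the mitosis list 21 of 25 were higher (25 adjusted over the list alone, median 1.31, camera adjusted p = 8.26e-11, and adjusted p = 0.168 with an estimated correlation) and in the naive list 13 of 15 were lower (13 adjusted over the list alone, median -0.72, camera adjusted p = 1.13e-06, and adjusted p = 0.161 with an estimated correlation). Immediate early and stress genes were higher in 16 of 19 cases and lower in 1 (16 and 1 adjusted over the list alone, median 1.50, camera adjusted p = 1.13e-06, and adjusted p = 0.161 with an estimated correlation).

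The largest rises from spleen to kidney included markers of other cells. H2-Aa, an MHC class II chain (chromosome 17, 34282744 to 34287823), was at 115 ± 80 nRPKM in the kidney and 0.374 ± 0.0921 in the spleen, Cd74 at 614 ± 415 against 8.62 ± 2.27, and the macrophage lysozyme gene Lyz2 at 97.97 ± 77.1 against 0.587 ± 0.668. H2-Ab1, H2-Eb1, the complement genes C1qa, C1qb and C1qc, Ccl3 and Ccl4 were also among the largest, with log2 differences of 4.26 to 5.22. All 16 macrophage markers (16 adjusted over the list alone, median 3.19, camera adjusted p = 4.31e-12, and adjusted p = 0.127 with an estimated correlation), all 8 dendritic cell markers (8 adjusted over the list alone, median 3.56, camera adjusted p = 4.82e-08, and adjusted p = 0.0786 with an estimated correlation) and 12 of 13 kidney tubule markers (12 adjusted over the list alone, median 1.47, camera adjusted p = 1.93e-07, and adjusted p = 0.103 with an estimated correlation) were higher in the kidney. Without the genes that followed the macrophage score, 3874 genes passed, and without those that share sequence with pseudogenes 3950 did. Lower in the kidney were Rps27rt, Lars2, Slc16a5, Galnt6os, TrnA, Rn18s, Scarna17, D8Ertd82e and Gpr83; of these Rps27rt is a copy of a ribosomal protein gene, Rn18s and TrnA are ribosomal and transfer RNA genes, and Galnt6os is antisense. The TrnA call was lost in 7 of 18 fits that left out a library. Among 80 ribosomal protein genes tested, 43 were higher and 5 lower in the kidney, and Rps25 (chromosome 9, 44407139 to 44410427), named after the values were seen, was at 173 ± 13.5 against 13.3 ± 1.15 nRPKM.

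Under anti-Ox40 the organs differed in 6156 genes, 3007 higher and 3149 lower in the kidney. Ifng, Tbx21, Gata3, Gzmb, Gzmk, Pdcd1, Tnfrsf4, Tnfsf4 and Mki67 were higher in the kidney, Gzmb by 2.97 and Ifng by 2.88 on the log2 scale, and Sell, Ccr7 and Cxcr5 were lower, by -1.38, -1.10 and -0.68. In the S phase and mitosis lists all 22 and all 25 members were higher in the kidney (22 and 25 adjusted over the list alone, medians 1.29 and 1.88, camera adjusted p = 9.02e-14 and 1.6e-13, and adjusted p = 0.132 and adjusted p = 0.156 with an estimated correlation). In the tissue residency list 14 of 17 were higher (14 adjusted over the list alone, median 1.25, camera adjusted p = 6.45e-08), and this list call held with an estimated correlation (adjusted p = 0.00875). The type I interferon list, higher in the kidney under control Ig, had 18 of 28 members lower there under anti-Ox40 and none higher (19 adjusted over the list alone, median -0.47, camera adjusted p = 0.000155, and adjusted p = 0.404 with an estimated correlation). Markers of other cells stayed higher: Lyz2 by 5.35, H2-Aa by 4.72 and C1qa by 4.19 on the log2 scale. Miox, an enzyme of kidney tubules (chromosome 15, 89334398 to 89337015), was at 15.4 ± 8.15 nRPKM in the kidney, and Aldob at 14.1 ± 5.50. Rps27rt was listed at 0 in all 5 kidney libraries with anti-Ox40, and Lars2, Dtx1, AW011738, Krt14, Treml2, Slfn8, Gpr83, Bach2os and Rnf213 made up the other large falls, with Rnf213, an interferon-induced gene, at 36.4 ± 9.30 against 114 ± 36.0 nRPKM. Across 12777 genes the organ differences under the 2 treatments had a Pearson r of 0.847 and a Spearman rho of 0.781. They shared 1809 genes higher in the kidney and 1531 lower, where independent lists would share 529 and 494.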

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

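Of the tests in this part, those on the depth and on the control Ig level of interferon genes, on CD8 T cell and NK markers, and on ribosomal protein genes were chosen after the result was seen. The covariates were chosen after the data were seen, and the tests with the macrophage score and depth were written down before their values were seen, as were the regroupings. The test of the difference and the estimated correlation were fixed before the data were examined.

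The effect of anti-Ox40 differed between kidney and spleen most clearly for interferon-response genes. By the test of the difference, Ifit3 differed by -2.88, Mx1 by -2.79, Ifi44 by -2.50, Oasl2 by -2.50, Rsad2 by -2.48 and Ifit1 by -2.23 on the log2 scale, and the medians were -1.24 for the type I list and -0.89 for the interferon gamma list. Cells of another type in the kidney libraries may dilute a response. With the macrophage score as a covariate the median type I difference was -1.35, with all 28 members past the threshold. This argues against a linear trend with macrophage markers within the groups. It cannot test cells present alike in both kidney groups, nor other cell types, so dilution stays open. Lower depth in the kidney is argued against by the 25 members at 10 nRPKM or more under control Ig, whose median kidney change was 0.24 (SD 0.19) where the spleen gave 1.56. Also open is whether a level already raised in the kidney limits the response. Under control Ig the list was higher there by a median of 0.91, with 23 of 28 members past the threshold singly. The list test, camera with an estimated correlation, gave an adjusted p of 0.161. A limit set by that level cannot be told apart from a weaker response in kidney cells. A difference between the organs, which the design names, also stays open.

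Gzmb rose with anti-Ox40 in the kidney by 2.96 on the log2 scale. CD8 T cells or NK cells that passed the sort could carry it. Of their markers, 12 had a median change of 0.0515 (SD 0.33), and the highest, Eomes, changed by 0.58. These values argue against a much larger share of such cells. They cannot show whether cells of these types already present raised Gzmb. The NK list also holds Tyrobp and Fcer1g, which followed the macrophage score (r = 0.98 and 0.92). With relative depth as a covariate the log2 fold change was 2.85 (adjusted p = 0.00398), and with the macrophage score it was 3.05 (adjusted p = 0.00495), so neither trend removed the rise. With the mitosis score, which itself separates the treatments, it was 1.92 and the call was lost (adjusted p = 0.67), so a link of the rise with proliferation stays open. A rise within CD4 T cells under the agonist is a hypothesis, and these tests do not separate it from a rise within other sorted cells. A larger share of a Gzmb-expressing CD4 subset and more Gzmb per cell were not tested against each other.

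Ribosomal protein genes counted higher in kidney than in spleen libraries, with a median log2 difference of 0.51 over 80 genes under control Ig and 3.60 for Rps25. Reads shared with near-identical pseudogenes, kept or dropped differently in the libraries of the organs, are a candidate explanation. Genes with 50% or more of their 50-base stretches in a pseudogene had a median absolute difference larger by 0.42 than those with under 10%, between the bounds of 0.5 and 0.2 set for the test, so it did not decide. Other genes had medians of -0.01 with under 10% (9668 genes), 0.20 in between (463) and 0.25 with 50% or more (37), a gradient of the same direction. The signed median was 0.74 over 21 genes with a large share, 0.45 over 50 in between and -0.18 over 9 genes with little shared sequence. The last value argues against a rise of the whole class in kidney cells, and whether the handling of the libraries, such as the added cleanup of kidney RNA, explains the pattern stays open.

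The difference test also singled out Scarna17 (1.82), Gzmc (1.53), Ctla2a (1.34), Mcm2 (0.94), Dapk2 (0.91) and Lsm3 (0.91), each with the higher effect in the kidney. Single libraries stood apart from the rest of their group in 8 of 178 groups of values examined, where chance gives about 8.9. In the kidney under control Ig, Il21 was at 9.23 nRPKM in replicate 4 (next 3.47), Il4 at 6.12 in replicate 3 (next 3.39), Gzmb at 8.82 in replicate 3 (next 5.55) and Acss2os at 5.85 in replicate 2 (next 4.33). In the spleen under control Ig, replicate 4 had Ifi44 at 1.46 nRPKM (next 0.821) and a type I interferon score of 3.70 (next 3.47). In the spleen under anti-Ox40, Rorc was at 0.739 nRPKM in replicate 4 (next 0.546), and the kidney tubule score was 0.236 in replicate 3 (next 0.197).

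Libraries were also regrouped at random in groups of the same sizes. In the kidney 1 of 100 splits, the real one, gave as many called genes as the 638 found, and the highest other gave 148. In the spleen 1 of 35 did so, with 1006 genes against 1. For the difference of effects 3 of 100 regroupings gave as many as the real 165, and the highest other gave 265, more than the real one. For kidney against spleen 1 of 100 gave as many in each treatment, 4253 against 2806 under control Ig and 6156 against 4772 under anti-Ox40, where the highest others moved 8 of the 9 libraries and so nearly mirror the real split. At 0.05 these splits argue against a chance arrangement of libraries for the kidney, spleen and organ counts. For the difference of effects the share was also under 0.05. Only 100 regroupings were drawn there and the highest, which moved 8 libraries, exceeded the real count. Relabelling within an organ leaves the real treatment effects in the values, so a high count can hold real signal. These regroupings therefore cannot decide for the difference of effects, and a chance arrangement is not excluded for it. Regrouping does not address libraries that share a mouse or an identifier run.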

How the results depend on the processing

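Most alternative settings were fixed before the data were examined; the covariates and the fits without pseudogene-sharing or macrophage-following genes were chosen after the data were seen. No paired analysis was possible because the labels carry no replicate numbers and tie no libraries to a mouse. The kidney count of 638 genes fell to 159 with no filter, where 21785 genes were tested, to 4 without the second run of identifiers, and rose to 1879 in one fit of all libraries, which borrows the smaller spread of the spleen. It lay between 153 (without anti-Ox40 replicate 5) and 891 (without anti-Ox40 replicate 4); it was 215 without anti-Ox40 replicate 2 and, without control Ig replicates 1 to 5 in turn, 208, 233, 333, 290 and 364. The spleen count of 1006 was 365 in one fit of all libraries, which borrows the larger spread of the kidney. It lay between 515 (without anti-Ox40 replicate 4) and 960 (without control Ig replicate 3), with 583 and 593 without anti-Ox40 replicates 2 and 3 and 592 without control Ig replicate 1. The difference count of 165 was 96 with no filter, 95 without the second run of identifiers, 289 with a separate spread per organ and 306 with the macrophage score as a covariate. It lay between 80 (without spleen anti-Ox40 replicate 4) and 392 (without kidney anti-Ox40 replicate 4), with 81 without spleen anti-Ox40 replicate 2 and 103 and 87 without spleen control Ig replicates 1 and 2. With the mitosis score as a covariate limma called 0 genes in the kidney (617 at an unadjusted p under 0.05) and 0 in the spleen (1204); this score separates the treatments, and Gzmb moved from 2.96 to 1.92 in the kidney and from 2.05 to 1.91 in the spleen, neither past the threshold. With that covariate the kidney medians of the cholesterol list and the immediate early list were -0.175 and 0.0786, and with the macrophage score that of the macrophage list was 0.14, each of the opposite sign. The cause was not tested where none is given. The correlation of effects, 0.320, was 0.267 over genes with a mean of 5 nRPKM or more and 0.383 with library weights, and 0.251 (without spleen anti-Ox40 replicate 3) to 0.384 (without kidney anti-Ox40 replicate 1). The organ counts stayed within 1.5 times of 4253 and 6156 under every alternative run, from 2923 to 5065 and from 4321 to 7312. Calls kept without each replicate numbered 32 of 69 named genes in the kidney, 64 of 94 in the spleen, 7 of 12 for the difference, and 27 of 30 and 32 of 32 between organs; for lists they were 16 of 21, 14 of 20, 9 of 11, 21 of 24 and 22 of 22. Of the 69 named kidney genes, Il2ra, Capg and Mcm6 stayed past the threshold in every alternative fixed before the data were examined. Members called without a replicate fell to 3 of 25 for the kidney mitosis list, 14 of 22 for S phase and 1 of 15 for naive T cells, and to 3 of 16 for the spleen regulatory list. Depth limits genes under about 1 nRPKM in the kidney, where 1 read in a gene of 2 kb was worth up to 0.0773 nRPKM.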

Other observations

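These genes and values were chosen after the data were seen, and all but Serpinb6b and Ifih1 were outside the lists fixed before. Lgals3 and Lgals7, which encode galectins (lectins that bind galactose-containing sugars), and Lgals3bp, which encodes a galectin-binding protein, rose with anti-Ox40 in both organs. Lgals3 was at 29.4 ± 10.4 against 12.8 ± 3.92 nRPKM in the kidney (log2 fold change 1.12) and at 5.79 ± 1.16 against 2.07 ± 0.623 in the spleen (1.15). Lgals7 rose by 1.29 and 1.60 and Lgals3bp by 0.48 and 1.11. Lgals1 rose in the kidney, from 190 ± 16.7 to 368 ± 62.4 nRPKM, and did not pass in the spleen (log2 fold change 0.25, adjusted p = 0.199). The protease inhibitor genes Serpina3g (1.07 and 0.98), Serpina3f (0.85 and 0.85) and Serpinb6b (0.64 and 0.31) rose in both organs, whereas Serpinb6a, Serpinc1, Serpinf1 and Serpini1 passed in neither. Serpina3f and Serpina3g are near-identical copies, and their split of reads is uncertain. Cish, a feedback inhibitor of cytokine signalling, rose from 22.2 ± 0.932 to 49.6 ± 8.10 nRPKM in the kidney and from 14.6 ± 0.690 to 23.1 ± 3.02 in the spleen. Ly6a, which encodes Sca-1, rose from 280 ± 50.1 to 458 ± 37.3 nRPKM in the kidney and from 129 ± 21.8 to 415 ± 74.2 in the spleen.

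Gcg was above all 9 control Ig libraries in all 9 anti-Ox40 libraries. It lay at 1.70 to 15.0 nRPKM in the kidney and 1.36 to 4.24 in the spleen under anti-Ox40, and at 0 to 0.642 and 0 to 0.049 under control Ig. Ifih1, an interferon-induced sensor of viral RNA, lies on the same chromosome but not directly beside Gcg (chromosome 2, 62595798 to 62646255). It rose by 1.28 in the spleen and had a log2 fold change of 0.28 in the kidney (adjusted p = 0.292). Dpp4, on the other side of Gcg (62330073 to 62412231), rose by 0.42 in the spleen and stood at -0.11 in the kidney. No explanation of the Gcg values was tested.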
